A study of Mus musculus with 103 samples.

How the data were processed

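Single mouse embryos of the FVB strain were collected at the 2-cell stage, 28 hours after intracytoplasmic sperm injection, lysed in TCL buffer and made into libraries with a Nextera single-cell RNA-seq kit, per the labels' protocols. Reads were handled with Bowtie and the mm10 genome, per the submitters' processing notes. Versions, the counting tool, the annotation and the use of strand are not given in the sources used here. The authors deposited 1 table of 7894 genes by 82 head and 21 whole-sperm embryos. No header names the unit, and the values were read as CPM, reads scaled to a fixed library size, as the authors deposited them, since the columns summed to 92.08 to 98.15% of a full library and low values in an embryo were multiples of a common step whatever the gene. Every gene kept had a value of at least 5 in the sorting column of the deposited table, so genes of low expression had been removed beforehand, and zeros were written as 0.1 (2.49% of values, with 9 values below that).

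The step gave the depth of each embryo, from 529863 to 6058308 reads, so that 1 read was worth 0.1651 to 1.8873 CPM. Of the lowest values of an embryo, above the value written for 0 and under 60 reads, a median of 87.2% came out as whole reads (80.3 to 90.4% over embryos, tolerance 0.001 reads), which was too few to treat them as counts, and tests were made on a log scale. Genes near 1 read per embryo carry large counting error, most of all in the head embryos, which were sequenced less deeply. A log2 fold change on the log2(CPM + 1) scale understates the change of low genes. Header rows of the table matched the labels for every embryo. Gene positions came from RefSeq on GRCm38.p6, the assembly also called mm10, by accession for 7846 genes and by symbol for 38, with 10 left without a position, and 11 symbols stored as dates were restored.

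Groups were taken from the labels. The 82 head embryos were fitted together with limma 3.58.1 in R 4.3.3 (limma-trend with robust moderation on log2(CPM + 1), genes at 5 CPM or more in at least 9 embryos, two-sided, Benjamini-Hochberg adjusted p under 0.05). The 21 whole-sperm embryos were fitted alone, and all embryos entered the test of source by preparation. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The score of a list in an embryo was the mean of log2(CPM + 1) over its members, compared with two-sided permutation tests of 100000 resamples and adjusted over 126 tests. The comparisons, lists, main tests, rule for named genes and the other settings listed first below were fixed before the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

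The genes named were the 8 largest rises and 8 largest falls past the threshold with a mean of at least 10 CPM, or the 3 of smallest p in each direction where none passed, and up to 2 members per direction of each list, or the 2 of smallest p. Of the lists, 14 had at least 5 members in the table. Lists below that were replication-dependent histone genes (4), cumulus markers (3), sperm transcripts (2), testicular somatic markers (1) and epididymal markers (1). Mitochondrially encoded genes, blood markers, sex-linked markers, Prm1 and Prm2 were not analysed here, so embryo sex was not tested. A gene that the rule names for whole sperm is not reported here.

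The limma step was tested on simulated data in which 200 genes were changed. Of genes changed 2-fold it recovered 42% in the diet comparison of cauda heads, 44% in that of rete heads, 44% and 42% in the source comparisons of Control and LP heads (7894 genes each) and 12% in that of whole sperm (7876 genes). At 4-fold it recovered 82, 82, 86, 86 and 78%, and it made 10, 2, 3, 6 and 6 false calls, among 7694 unchanged genes in the head comparisons and 7676 in whole sperm. The simulated genes varied independently of each other, so these figures do not show the error where genes move together. Other splits of the real embryos called up to 1864 genes for diet in rete heads and 831 for source in Control heads.

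Other settings were pseudocounts of 0.1 and 5, no filter and a filter at 10 CPM, quantile normalization, median-of-ratios scaling, weights per embryo, the number of detected genes as a covariate, leaving out embryos more than 3 median absolute deviations low in detected genes, the replicate number as a block, other embryos in the fit, a rank-sum test and a threshold of 0.1. Settings chosen after seeing the data were a stage index as a covariate (the ribosome biogenesis score minus the maternal score), near-identical pairs averaged, centring within 20 bins of GC content or transcript length (available for 99.5% of genes), and scores of other lists. Embryos with very low ribosomal scores were also counted after seeing the data, and none was left out for its score. For each comparison 100 splits of the embryos were drawn. Labels of embryo number were checked for neighbouring embryos that resembled each other. Rete LP embryos 20 and 21 correlated at r = 0.973, with a chi-square per gene of 4.39. Sampling noise gives 1, and the median over pairs within groups was 38.3. A value above 1 argues only against a library deposited more than once and does not show these embryos to be independent. They were counted separately in the main tests and averaged in another setting.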

Results

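Messenger RNA was measured in single mouse embryos of the FVB strain at the 2-cell stage, 28 hours after intracytoplasmic sperm injection, in which a sperm or its head is injected directly into an oocyte. The injected sperm came either from the rete testis, where sperm leave the testis, or from the cauda epididymis, where mature sperm are stored. The sperm donors had been fed a Control or a Low Protein (LP) diet and the oocyte donors a Control diet. Of the 82 embryos made with sperm heads, 20 came from cauda heads of Control males, 17 from cauda heads of LP males, 22 from rete heads of Control males and 23 from rete heads of LP males. Whole sperm gave 21 embryos, 9 from cauda sperm and 12 from rete sperm. For these 21 embryos the sperm donors' diet is given as Control only in the file header. The labels name neither the father nor the day of injection, so every p-value measures the spread between embryos only.

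Expression was read as CPM, reads per gene scaled to the same library size in every embryo, for 7894 genes. The depth recovered from the spacing of low values ran from 529863 to 6058308 reads per embryo. Its median was 1111768 reads in cauda Control, 1056545 in cauda LP, 1104056 in rete Control and 1197679 in rete LP head embryos. Whole-sperm embryos were deeper, with medians of 4091157 reads for cauda and 2806572 for rete sperm. The number of genes at 1 CPM or more was 7632 ± 168 (SD, n = 20), 7692 ± 104 (n = 17), 7614 ± 184 (n = 22) and 7582 ± 360 (n = 23) in these 4 head groups, and 7563 ± 347 (n = 9) and 7690 ± 144 (n = 12) in the whole-sperm groups. The lowest number was 6095, in rete LP embryo 11. Below, a log2 fold change is on the scale of log2(CPM + 1) and is given ± its standard error, and CPM values are means ± SD.

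The LP diet was compared with the Control diet first in embryos made with rete sperm heads, 23 against 22, to ask whether a father's diet alters early embryonic mRNA before sperm pass through the epididymis. Hspbap1, which encodes a protein that binds a small heat-shock protein, fell from 22.2 ± 16 to 5.06 ± 5.05 CPM (log2 fold change -2.20 ± 0.39, limma adjusted p = 3.12e-04), and all 23 LP embryos lay below the Control median. Obox2, an oocyte-specific homeobox gene, fell from 158 ± 116 to 59.2 ± 26.9 CPM (-1.25 ± 0.27, adjusted p = 0.00929), again with 23 of 23 LP embryos below the Control median. Gnpda2, a glucosamine-6-phosphate deaminase, fell from 52.7 ± 59.7 to 10.2 ± 9.71 CPM (-2.02 ± 0.46, adjusted p = 0.0141). Usp22, a histone deubiquitinase, rose from 320 ± 286 to 580 ± 316 CPM (2.26 ± 0.61, adjusted p = 0.0347), with 18 of 23 LP embryos above the Control median. Xpot, the nuclear export receptor for tRNA, rose from 32.5 ± 28.6 to 66.6 ± 36.9 CPM (1.74 ± 0.49, adjusted p = 0.0456), with 22 of 23 above it. The log2 fold changes of Usp22 and Xpot are larger than the ratios of their CPM means, because a mean of logs gives more weight to low embryos. Usp22 was also among the genes at the late end of the largest axis of variation, described under other observations. Over 16 alternative settings Hspbap1 passed in 16, Obox2 in 15, Gnpda2 in 13, Usp22 in 11 and Xpot in 10, and the log2 fold change of Usp22 ran from 0.63 to 2.54 (adjusted p = 0.017 to 0.296).

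Among 7894 genes tested, 118 passed in this comparison, 31 higher and 87 lower in LP embryos. The other genes with the largest rises were 1600012H06Rik (2.03 ± 0.57), the zinc-finger gene Yy2, an intronless relative of Yy1 that can share reads with it (1.77 ± 0.49), the nuclear import receptor Tnpo3 (1.73 ± 0.49), the exchange factor Mcf2 (1.62 ± 0.41), the GTP-binding protein gene Gnl1 (1.58 ± 0.44) and Gpkow (1.58 ± 0.39). The other largest falls were in Ildr1 (-1.94 ± 0.50), the DNA crosslink repair gene Dclre1a (-1.80 ± 0.48), the Ras-family gene Diras2 (-1.79 ± 0.49), the lysosomal potassium channel gene Tmem175 (-1.76 ± 0.37), Mreg (-1.74 ± 0.49) and Ptov1 (-1.73 ± 0.41). In the mm10 assembly, Hspbap1 lies on chromosome 16 at 35769726 to 35828462, Obox2 on chromosome 7 at 15388851 to 15398545 and Gnpda2 on chromosome 5 at 69574998 to 69592332. Usp22 lies on chromosome 11 at 61151781 to 61175059 and Xpot on chromosome 10 at 121587380 to 121626506. The count and its direction moved with the scaling: 143 genes were higher and 149 lower after quantile normalization, and 217 higher and 131 lower after median-of-ratios scaling, against 31 and 87 without either. It was 14 genes when only these 2 groups entered the fit and 346, 214 higher and 132 lower, without the embryos of few detected genes (cauda Control 19, rete Control 17 and rete LP 11), while with the stage index as a covariate 1 of the 31 higher and 22 of the 87 lower genes stayed past the threshold.

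The mean level of ribosome production genes was higher in LP than in Control embryos, and part of the Control embryos lay far below the rest. The ribosome biogenesis score was more than 3 median absolute deviations below the median of head embryos in 6 of 22 Control embryos (4, 8, 12, 14, 15 and 17, from 3.55 to 5.10) and in 1 of 23 LP embryos (11, at 3.83), and the group medians were 6.84 and 7.22. Of 55 ribosome biogenesis and nucleolar genes, 1 rose, none fell and 54 did not pass, while 16 passed when adjusted over the list alone and 53 had a positive log2 fold change (median 0.69). The riser was Nop14, needed for small ribosomal subunit assembly, at 33.8 ± 20.6 CPM in Control and 68.2 ± 37.9 CPM in LP embryos (1.32 ± 0.35, adjusted p = 0.0304). None of 81 cytosolic ribosomal protein genes passed by limma, also adjusted over the list alone (0), although 74 were positive, and their smallest p belonged to Rps3a1 (1.04 ± 0.33, adjusted p = 0.0737). The camera test with a preset correlation called both lists higher (adjusted p = 1.47e-11 and 1.33e-08), and neither call held with an estimated correlation (adjusted p = 0.818 for each). The mean score of the ribosome biogenesis list per embryo was 6.99 ± 0.89 in LP and 6.27 ± 1.34 in Control embryos, a difference of 0.72 ± 0.34 (two-sided permutation p = 0.0385, 0.252 after adjustment over 126 tests), with 16 of 23 LP embryos above the Control median.

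Transcripts laid down in the oocyte lay lower. Of 72 oocyte-derived maternal transcripts, none rose, 5 fell and 67 did not pass, and 20 passed when adjusted over the list alone, with 61 negative log2 fold changes (median -0.44). The 5 were Bcl2l10, a Bcl2-family gene of oocytes (-1.28 ± 0.33, from 902 ± 1140 to 252 ± 176 CPM), Obox2, the linker histone gene H1foo (-1.17 ± 0.31), the subcortical maternal complex gene Ooep (-0.90 ± 0.25) and the oocyte-secreted protein gene Oosp3 (-0.88 ± 0.23). H1foo, Ooep and Oosp3 were singled out after their values were seen, and Obox2 belongs to a family of similar copies among which reads may be divided. The preset camera test gave an adjusted p of 1.01e-08 and camera with an estimated correlation an adjusted p of 0.818, whereas fry, which asks only whether the set moves one way, gave p = 0.00344 (adjusted p = 0.0482). Per embryo the maternal score was 7.27 ± 0.40 in LP and 7.73 ± 0.54 in Control embryos (difference -0.46 ± 0.14, permutation p = 0.00231, adjusted p = 0.155), and 2 of 23 LP embryos lay above the Control median. The 6 Control embryos of very low ribosome biogenesis score had maternal scores from 8.08 to 8.73, where the Control median was 7.78.

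Smaller numbers passed in other lists. Eed, a Polycomb repressive complex subunit (-0.66 ± 0.18), and Pcbp1, a poly(C)-binding protein gene (-0.71 ± 0.19), fell among 50 RNA-processing and chromatin regulators, of which none rose and 5 passed when adjusted over the list alone. Gnas (-1.36 ± 0.35) and the potassium channel gene Kcnq1 (-1.44 ± 0.39) fell among 11 maternally expressed imprinted genes (none rose, 2 adjusted over the list alone), and each locus also carries an overlapping antisense RNA, so that reads from either strand are counted together if strand was not used. Atp5l (-1.33 ± 0.35) and Ndufa10 (-1.18 ± 0.30), subunits of ATP synthase and complex I, fell among 54 oxidative phosphorylation genes (none rose, 3 adjusted over the list alone), and Apaf1, a core apoptosome gene, rose (1.36 ± 0.38) among 14 p53 and DNA-damage response genes (none fell, 1 adjusted over the list alone). Camera called none of these 4 lists (adjusted p = 0.818 for each with an estimated correlation). Of the 3 cumulus cell markers in the table, Serpine2 fell (-1.39 ± 0.36), and Amhr2 and Gja1 did not pass. Among the 49 MERVL-linked 2-cell genes, 0 passed by limma, over all genes or adjusted over the list alone, and 28 were positive. The smallest p-values belonged to Pramef25 (0.80 ± 0.29) and Pramel7 (1.5 ± 0.59), and the score differed by 0.17 ± 0.21 (permutation adjusted p = 0.769). In 6 further lists 0 genes passed over all genes by limma. Adjusted over the list alone, 2 of 19 pluripotency and first-lineage genes, 2 of 15 DNA methylation and imprint-protection genes, 3 of 20 heat-shock and unfolded-protein genes and 1 of 13 glycolysis genes passed. None of 18 sterol synthesis genes and none of 9 paternally expressed imprinted genes did so. Their members of smallest p included Tbx3 (0.89 ± 0.30), Zfp57 (-0.63 ± 0.20), Hsph1 (1.33 ± 0.41), Slc2a3 (1.38 ± 0.40), Sqle (0.46 ± 0.22) and Snurf (-1.45 ± 0.56). Camera with an estimated correlation gave adjusted p = 0.933 for sterol synthesis and 0.818 for the other 5. Markers of other cells in the table were at 0.46 ± 0.22 (Odf2, sperm), 0.03 ± 0.41 (Ldhc, sperm), 0.84 ± 0.49 (Gata4, testicular somatic cells) and -0.38 ± 0.27 (Aqp9, epididymis). The replication-dependent histone genes of smallest p were Hist1h2ao (0.58 ± 0.31) and Hist2h3c1 (-0.68 ± 0.39), and none of these 6 passed. The plot of named genes shows those that the naming rule gave and that passed in rete heads, beside their values for cauda heads.

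**Figure D1:**
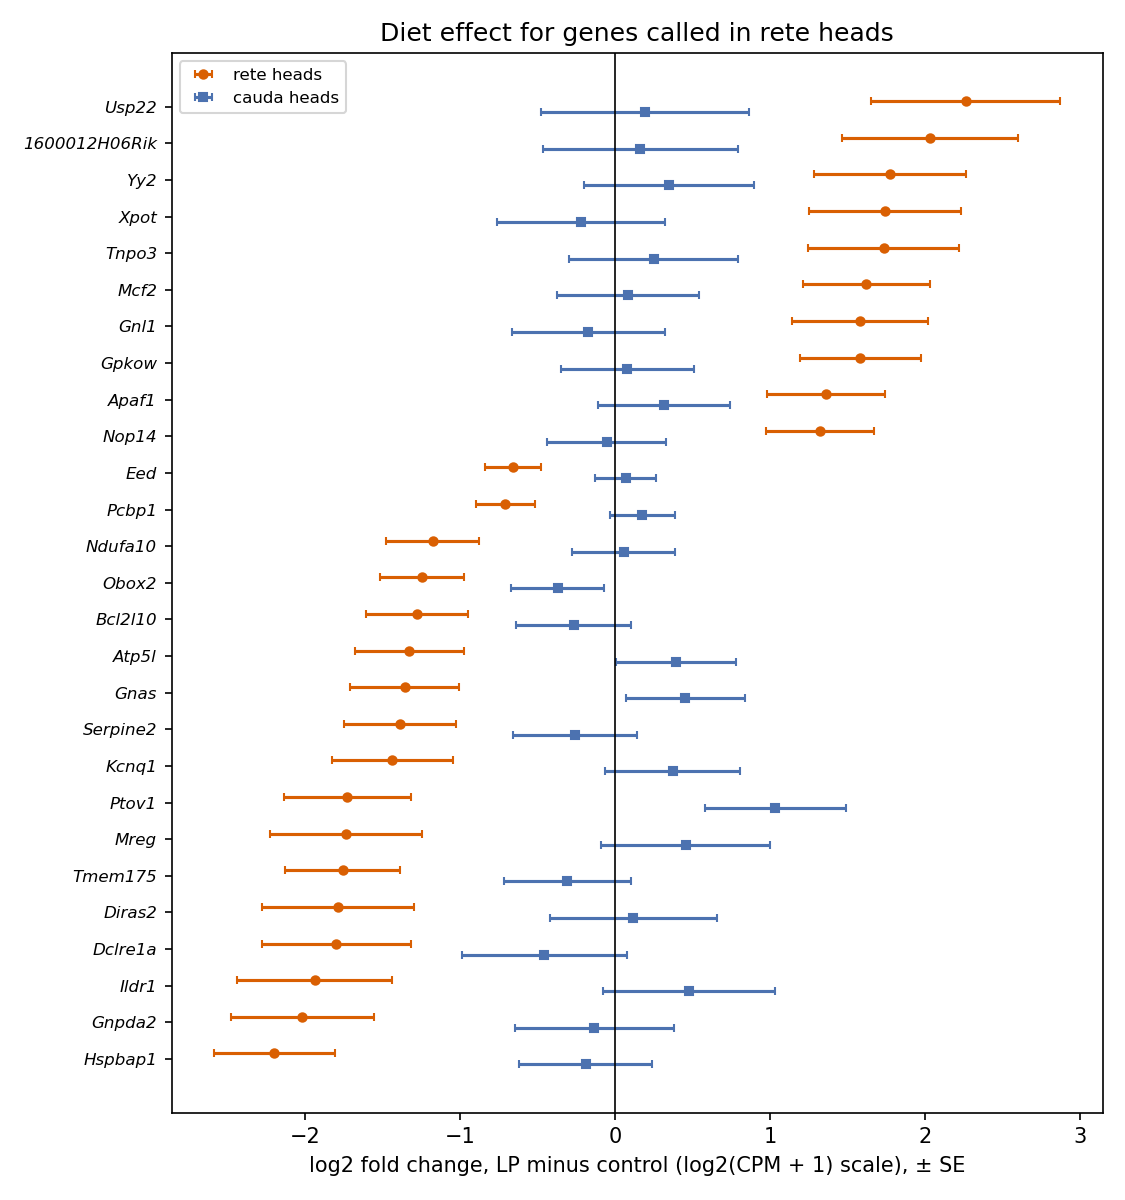
Log2 fold change (LP minus Control, log2(CPM + 1) scale) ± SE of the genes that the naming rule gave and that passed in rete sperm head embryos (orange, 23 LP against 22 Control), with the same genes in cauda sperm head embryos (blue, 17 against 20). Rete values run from -2.20 for Hspbap1 to 2.26 for Usp22.

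In embryos made with cauda sperm heads, 17 LP against 20 Control, no gene passed by limma. The smallest p on the positive side belonged to Ybx1, a cold-shock domain RNA-binding protein gene (0.83 ± 0.20, 1010 ± 303 against 616 ± 273 CPM), Rac1, a regulator of the actin cytoskeleton (1.03 ± 0.29), and Zmynd19 (0.65 ± 0.19). On the negative side it belonged to the deubiquitinase gene Usp47 (-0.80 ± 0.28), Rnf219 (-1.32 ± 0.48) and the nucleoporin gene Nup54 (-0.88 ± 0.32), and none of these 6 passed (smallest adjusted p 0.546). With 0 genes past the threshold by limma, 163 of 7894 had an unadjusted p under 0.05, where 395 would be expected if no gene differed. The count was 301 with only these 2 groups in the limma fit and 350 by rank-sum test. Genes are not independent, which widens the spread of such counts, and 46 of 100 splits of the embryos gave as many (median of other splits 148). The rank-sum test also called 0, and limma with array weights called 14, all higher in LP embryos. Of the 14 lists, maternal transcripts had 53 of 72 members negative (median -0.21, 0 adjusted over the list alone, preset camera adjusted p = 2.68e-05), and this call was lost with an estimated correlation (adjusted p = 0.674). Glycolysis genes had 2 of 13 positive (median -0.27, camera adjusted p = 0.00458, adjusted p = 0.554 with an estimated correlation). Eno1 and Aldoa had the smallest p among them (-0.66 ± 0.38 and -0.42 ± 0.27). Of p53 and DNA-damage response genes 11 of 14 were positive (camera adjusted p = 0.0265, 0.555 with an estimated correlation). Of MERVL-linked genes 15 of 49 were positive (0.0016 and 0.893, in the same order). Both lists had 0 adjusted over the list alone. Across genes, which are not independent, the cauda and rete diet effects correlated with r = 0.047, and 85 of 100 permutations of diet labels gave a correlation as extreme.

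The difference between the diet effects in rete and cauda heads was tested as an interaction. It passed for 15 genes, all with a negative interaction, a positive diet difference in cauda heads and a negative diet difference in rete heads. These genes lie outside the naming rule and are named because they passed. Akirin2, a nuclear factor that links transcription and chromatin, had the smallest p (interaction -2.35 ± 0.33, adjusted p = 2.03e-06). Its mean was 88.7 ± 51.1 CPM in cauda Control (n = 20), 150 ± 68.5 in cauda LP (n = 17), 225 ± 138 in rete Control (n = 22) and 72.1 ± 30.4 in rete LP embryos (n = 23). For Akirin2, 14 of 17 cauda LP embryos lay above the cauda Control median while 23 of 23 rete LP embryos lay below that of rete Control. Rac1 (-2.31 ± 0.39, adjusted p = 1.57e-04), Zmynd19 (-1.67 ± 0.26, adjusted p = 1.58e-05) and the ubiquitin ligase gene Siah2 (-1.77 ± 0.29, adjusted p = 7.13e-05) followed. Akirin2 lies on chromosome 4 at 34550615 to 34566965, Zmynd19 on chromosome 2 at 24949777 to 24960870, Siah2 on chromosome 3 at 58674949 to 58692439 and Rac1 on chromosome 5 at 143505481 to 143528031.

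The other 11 were the phosphatase gene Pdxp (-2.77 ± 0.52), the cell-cycle transcription factor E2f1 (-1.85 ± 0.38), Ybx1 (-1.29 ± 0.27), the mRNA export adaptor Alyref (-2.54 ± 0.54), the lactosylceramide synthase gene B4galt6 (-2.38 ± 0.51), the transcription factor Tfap2e (-2.39 ± 0.53), the histone methyltransferase Suv39h2 (-1.56 ± 0.34), Ptov1 (-2.76 ± 0.61), the GTPase Arf6 (-1.98 ± 0.46), the splicing factor Srsf2 (-1.95 ± 0.47) and the RNA-binding protein gene Grsf1 (-1.52 ± 0.37). Of the 15, 10 also fell in the rete diet comparison, which is part of the interaction. None of the 15 passed in the cauda diet comparison by limma. Ybx1 has processed pseudogenes that can take its reads. Ybx1, Arf6 and Grsf1 no longer passed after centring within bins of GC content (-1.21 ± 0.31, -1.79 ± 0.48 and -1.41 ± 0.41, adjusted p = 0.0651, 0.106 and 0.174) or of transcript length (adjusted p = 0.0871, 0.14 and 0.155), nor Srsf2 after the latter (-1.84 ± 0.46, adjusted p = 0.0544). Of the 15, 13 passed with median-of-ratios scaling and 14 without the embryos of few detected genes or with near-identical pairs averaged, whereas array weights called 74 genes, 7 positive and 67 negative, and the stage index as a covariate 42. Ribosome biogenesis genes had 53 of 55 interactions positive (median 0.69, 0 over all genes and 0 adjusted over the list alone), with a preset camera adjusted p of 5.98e-11 and an adjusted p of 0.859 with an estimated correlation. The 6 rete Control embryos with ribosome biogenesis scores from 3.55 to 5.10 entered this test. Camera with the preset correlation also called ribosomal protein genes (70 of 81 positive, adjusted p = 2.36e-06), MERVL-linked genes (40 of 49, 0.00286), maternal transcripts (19 of 72, 0.012) and heat-shock and unfolded-protein genes (11 of 20, 0.0321), each with 0 adjusted over the list alone and an adjusted p = 0.859 with an estimated correlation.

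**Figure D2:**
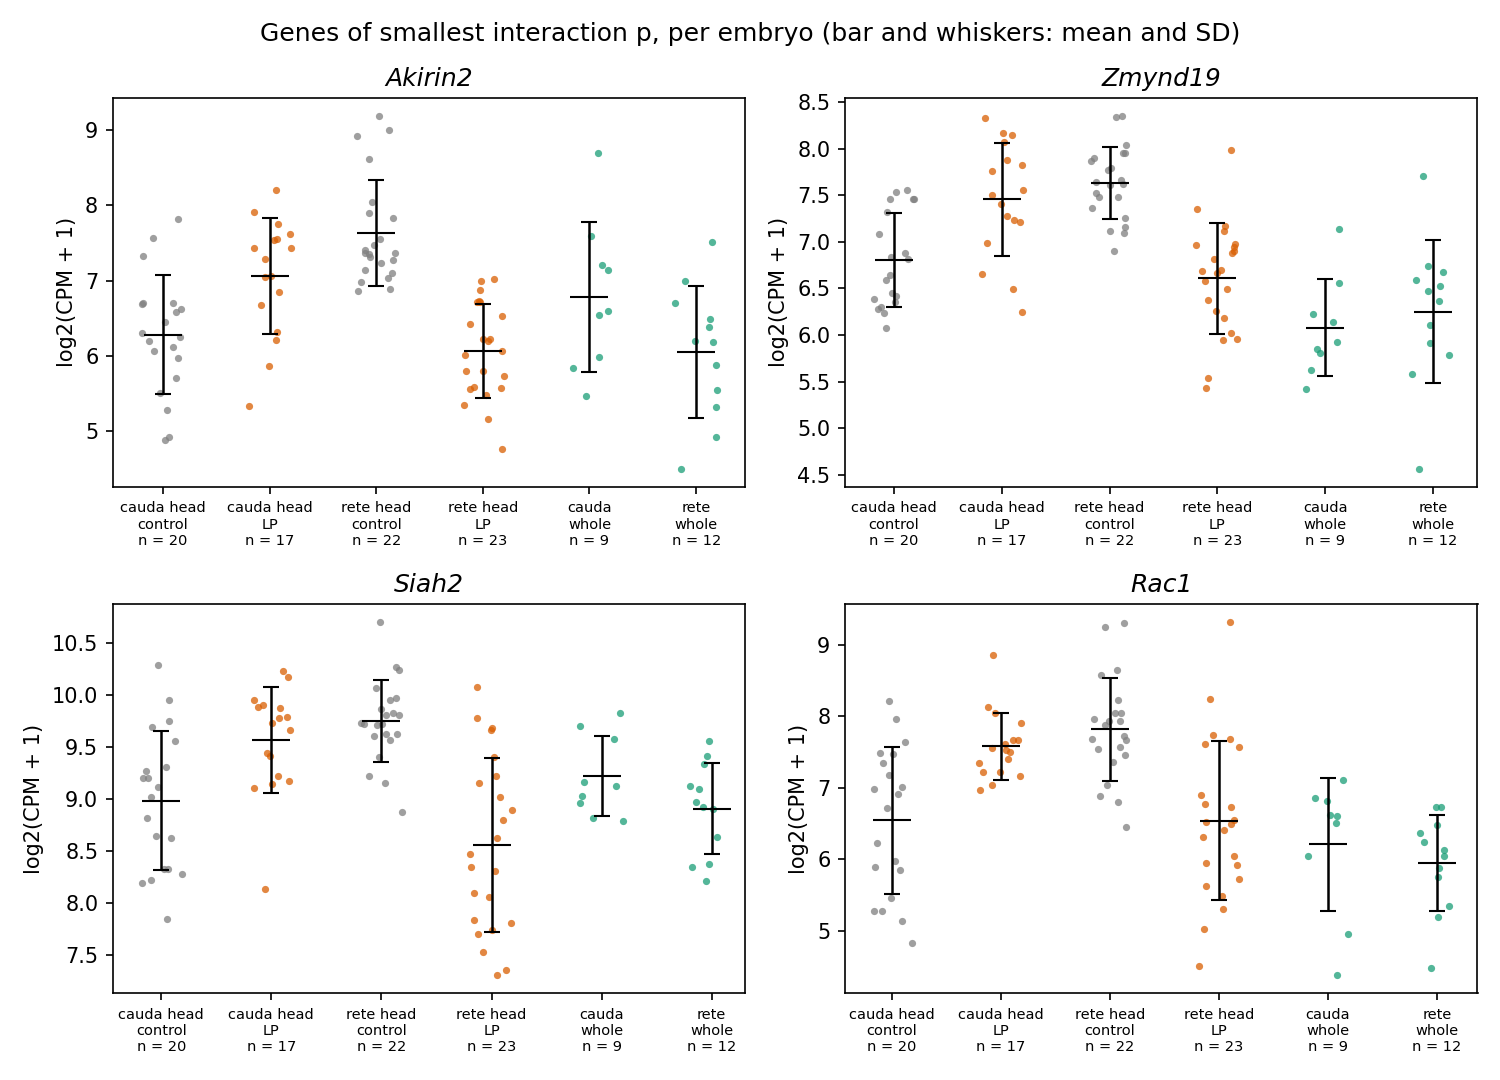
Level of Akirin2, Zmynd19, Siah2 and Rac1 in each embryo, as log2(CPM + 1) on the vertical axis, in the 6 groups along the horizontal axis (grey Control, orange LP, green whole sperm). Bars and whiskers are means and SD. For Akirin2 the group means of log2(CPM + 1) are 6.28 in cauda Control, 7.07 in cauda LP, 7.63 in rete Control and 6.07 in rete LP embryos.

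Rete and cauda sperm heads of Control males, 22 against 20 embryos, were compared to ask whether passage through the epididymis alters embryonic mRNA. Akirin2 rose in rete embryos (1.35 ± 0.23, adjusted p = 5.40e-04, 22 of 22 above the cauda median), as did Rac1 (254 ± 142 against 116 ± 76.7 CPM, 1.27 ± 0.27, adjusted p = 0.0323) and Zmynd19 (204 ± 55.6 against 118 ± 42.7 CPM, 0.82 ± 0.18, adjusted p = 0.0323). These were the 3 genes that passed. Over 16 alternatives Akirin2 passed in 16, Zmynd19 in 13 and Rac1 in 10, and of the 3 Akirin2 alone passed after centring by GC content, after centring by length and with the stage index as a covariate, where Rac1 was at 0.97 ± 0.26 and Zmynd19 at 0.74 ± 0.18 (adjusted p = 0.182 and 0.129, their highest over the alternatives). Array weights called 17 genes, 13 higher and 4 lower. An unadjusted p under 0.05 was reached by 1745 of 7894 genes, 456 higher and 1289 lower in rete embryos, and the rank-sum test called 3 genes. Akirin2, Rac1 and Zmynd19 were all among the 15 interaction genes. The interaction equals the source difference in LP heads minus that in Control heads, so this overlap is not separate evidence. Their source difference had the opposite sign in LP heads. It was -1 ± 0.24, -1.04 ± 0.28 and -0.85 ± 0.18 there, and Zmynd19 alone passed (limma adjusted p = 0.0216). In whole sperm it was -0.73 ± 0.38, -0.26 ± 0.34 and 0.18 ± 0.31, and none of them passed.

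The mean level of ribosome production genes was lower in rete than in cauda Control embryos. The same 6 of 22 rete embryos, and 1 of 20 cauda embryos (23, at 4.32), had the very low ribosome biogenesis scores described above, and the group medians were 6.84 and 7.29. The ribosomal protein score was as far below in 4 rete embryos (4, 8, 12 and 14) and in cauda embryo 23, with group medians of 6.21 and 6.96. All 81 cytosolic ribosomal protein genes, many of which share reads with pseudogenes, had a negative log2 fold change (median -0.73), 0 passed over all genes by limma and 38 passed when adjusted over the list alone. Rps4l was at 64.4 ± 70.5 CPM in rete and 105 ± 59.9 CPM in cauda embryos (-1.68 ± 0.47), and Rps27 differed by -1.56 ± 0.46 on the log2 scale. All 55 ribosome biogenesis genes were negative (median -0.82), 0 over all genes and 24 adjusted over the list alone, among them Utp6 (-1.02 ± 0.32) and Rpf2 (-1.73 ± 0.55). Maternal transcripts had 59 of 72 members positive (median 0.31, 0 over all genes and 0 adjusted over the list alone), among them Oosp3 (0.70 ± 0.24) and Zbed3 (1.04 ± 0.37). Preset camera called the 3 lists (adjusted p = 2.34e-16, 1.12e-12 and 3.38e-08), and no call held with an estimated correlation (adjusted p = 0.626 for each). The ribosomal protein score was 5.97 ± 1.27 in rete and 6.71 ± 0.78 in cauda embryos (-0.74 ± 0.32, permutation p = 0.0288, adjusted p = 0.242), and 5 of 22 rete embryos lay above the cauda median. Quantile and median-of-ratios scaling left the direction of these 3 lists as it was. The plot of list scores shows the embryos behind these means.

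**Figure D3:**
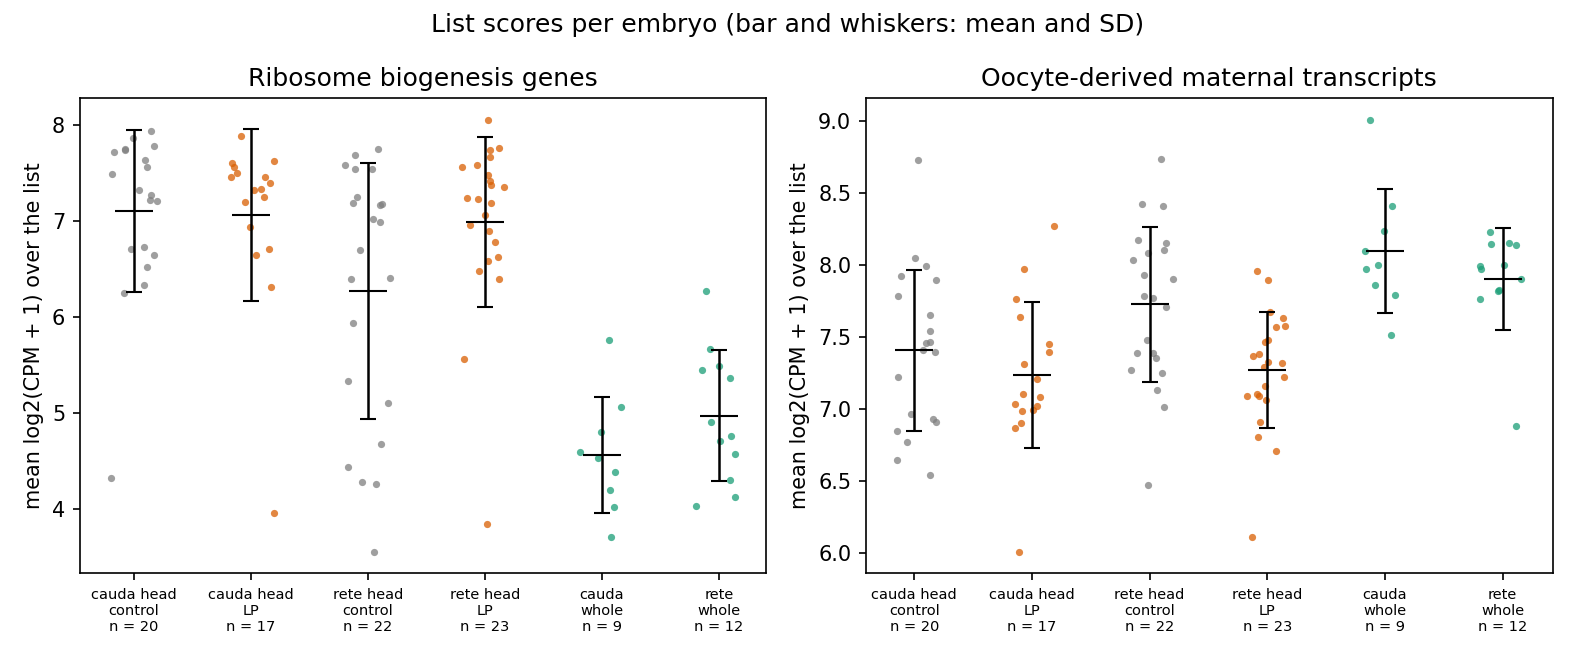
Score per embryo, the mean of log2(CPM + 1) over the list, for ribosome biogenesis genes (left) and oocyte-derived maternal transcripts (right), in the 6 groups (points are embryos, bars and whiskers means and SD). The ribosome biogenesis score runs from 3.55 to 7.75 in rete Control embryos, with mean 6.27 against 7.10 in cauda Control embryos.

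Between rete and cauda heads of LP males, 23 against 17 embryos, 6 genes fell in rete embryos and none rose. Hspbap1 fell from 22.1 ± 18.6 to 5.06 ± 5.05 CPM (-2.08 ± 0.41, adjusted p = 0.0111), Mreg from 41.8 ± 37.4 to 8.51 ± 10.6 CPM (-2.34 ± 0.53, adjusted p = 0.0357) and Pdxp from 84.8 ± 42.2 to 29.6 ± 28.9 CPM (-1.97 ± 0.37, adjusted p = 0.0067). The tankyrase gene Tnks2 (-1.62 ± 0.34), Siah2 (-1.01 ± 0.21) and Zmynd19 (-0.85 ± 0.18) also fell, with adjusted p = 0.0117, 0.0117 and 0.0216. Of the 23 rete embryos, 23 lay below the cauda median for Hspbap1, 22 for Mreg, Tnks2 and Zmynd19, and 21 for Pdxp and Siah2. The same 23 embryos entered the diet comparison of rete heads, so a fall of Hspbap1 in both is not separate evidence. MERVL-linked 2-cell genes had 39 of 49 members positive (median 0.36), 0 over all genes by limma and 1 adjusted over the list alone, the deubiquitinase-family gene Usp17ld (1.5 ± 0.41), while Zscan4c was at 344 ± 662 CPM in rete and 96.5 ± 100 CPM in cauda embryos (1.33 ± 0.47). Both belong to families of near-identical copies. Preset camera gave this list an adjusted p of 2.93e-13, lost with an estimated correlation (adjusted p = 0.475), and the score differed by 0.38 ± 0.24 (permutation p = 0.102). Oxidative phosphorylation genes had 9 of 54 positive (median -0.20, 3 adjusted over the list alone, camera adjusted p = 0.0246, 0.866 with an estimated correlation), led by Sdhd (-1.71 ± 0.43, adjusted p = 0.0833), and 5 of 81 ribosomal protein genes were positive (0 adjusted over the list alone, 0.00411 and 0.95). Maternal transcripts had a median of -0.01 and a mean of 0.03, and camera placed them higher (adjusted p = 0.00633, adjusted p = 0.866 with an estimated correlation), so that median and test differed in sign. With only the 2 groups in the fit 0 genes passed, median-of-ratios scaling, the rank-sum test and centring by GC content gave 3 genes each and centring by length 1. Array weights called 260 genes, 82 higher and 178 lower, the stage index as a covariate 16, a pseudocount of 5 gave 11, leaving out the embryos of few detected genes 10 and a threshold of 0.1 gave 13.

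Whole sperm from the rete and the cauda, 12 against 9 embryos, gave no gene past the threshold by limma. Klrg2 was at 23.6 ± 21.2 CPM in rete and 2.31 ± 3.10 CPM in cauda embryos (2.76 ± 0.65), and the cytokine-signalling inhibitor Socs3 at 94.3 ± 47.7 and 37.6 ± 41.6 CPM (1.98 ± 0.50). Arl6ip1 (-0.81 ± 0.22), Blcap (-1.15 ± 0.33) and Zfp664 (-0.94 ± 0.27) had the smallest p on the negative side (limma adjusted p = 0.524 for each of these 5). With 0 calls by limma, 662 of 7782 genes had an unadjusted p under 0.05, where 389 would be expected if no gene differed, and the rank-sum test also called 0. Splits of the embryos gave as many unadjusted genes in 14 of 100 (median of other splits 310). Ribosomal protein genes had 73 of 77 members positive (median 0.62), MERVL-linked genes 45 of 49 (median 0.39) and ribosome biogenesis genes 40 of 55 (median 0.34), with 0 adjusted over the list alone in each. Heat-shock and unfolded-protein genes had 17 of 20 positive (median 0.39), among them Hspa1a (1.68 ± 0.60), and maternal transcripts 21 of 72 (median -0.24). Preset limma camera called these 5 (adjusted p = 7.09e-10, 5.35e-04, 0.0316, 0.0218 and 4.02e-04), and none of the calls held with an estimated correlation (limma adjusted p = 0.536, 0.621, 0.679, 0.536 and 0.536).

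Averaged over both sources, the LP diet moved no gene past the threshold in the 82 head embryos. The repair and iron-sulphur gene Mms19 (1.16 ± 0.30, 52.0 ± 26.9 against 27.5 ± 21.3 CPM), the translation factor Eif4g2 (0.51 ± 0.13) and the kinesin gene Kif4 (0.61 ± 0.17) had the smallest p on the positive side. Hspbap1 (-1.20 ± 0.29), Rnf181 (-0.71 ± 0.17) and the ciliary gene Bbs4 (-0.80 ± 0.20) had it on the negative side (adjusted p = 0.174 for each of these last 3). By limma 0 genes passed, also with array weights, and 801 had an unadjusted p under 0.05. No rank-sum test was run for averaged effects. Maternal transcripts had 62 of 72 members negative (median -0.33, 7 adjusted over the list alone, preset camera adjusted p = 6.13e-13, adjusted p = 0.306 with an estimated correlation, fry p = 0.0062 and adjusted p = 0.0868), led by Obox2 (-0.81 ± 0.20) and Pabpn1l (-1.06 ± 0.31). Their score differed by -0.31 ± 0.11 (permutation p = 0.00714, adjusted p = 0.158), and 10 of 40 LP embryos lay above the Control median. Preset camera also called ribosome biogenesis genes (51 of 55 positive, 0 adjusted over the list alone, adjusted p = 3.60e-07), ribosomal protein genes (74 of 81, 0, 1.08e-06) and p53 and DNA-damage response genes (10 of 14, 2, 0.0296), with adjusted p = 0.827, 0.827 and 0.585 with an estimated correlation. The 6 rete Control embryos with ribosome biogenesis scores from 3.55 to 5.10 and maternal scores from 8.08 to 8.73 were among the Control embryos.

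Averaged over both diets, rete against cauda heads gave 0 genes past the threshold by limma and 1341 with an unadjusted p under 0.05. Limma with array weights called 484, 150 higher and 334 lower in rete embryos. Zfp109 (1.43 ± 0.37), Gm10248 (1.07 ± 0.29) and AU016765 (1.09 ± 0.30) were on the positive side, and Tssc1 (-1.39 ± 0.30, adjusted p = 0.0844), the complex II gene Sdhd (-1.29 ± 0.30) and the energy-sensing kinase gene Prkaa1 (-1.18 ± 0.28) on the negative side. All 81 ribosomal protein genes were negative (median -0.50, 0 over all genes, 21 adjusted over the list alone), with a preset camera adjusted p of 1.78e-16 and 0.62 with an estimated correlation. Rete Control embryos 4, 8, 12 and 14, with ribosomal protein scores from 2.91 to 4.27, were among the rete embryos. Oxidative phosphorylation genes had 13 of 54 positive (median -0.30, 3 adjusted over the list alone, 0.0107 and 0.645), including Sdhd and Ndufs3 (-0.86 ± 0.22). Preset camera also called ribosome biogenesis genes (0 of 55 positive, adjusted p = 1.01e-06), maternal transcripts (59 of 72, 1.87e-09) and MERVL-linked genes (35 of 49, 2.10e-07), with 0 adjusted over the list alone in each and adjusted p = 0.645, 0.62 and 0.62 with an estimated correlation.

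The source effect was also compared between whole sperm and heads. By limma 0 genes passed (smallest adjusted p 0.0876), and 1011 of 7894 had an unadjusted p under 0.05, 934 of them positive. Limma called 237 genes with array weights, 234 of them positive, and 15 with a pseudocount of 0.1, all positive, 12 at a threshold of 0.1 and 1 each after centring by GC content and by length. The interaction was positive for 81 of 81 ribosomal protein genes (median 1.11, 0 over all genes, 34 adjusted over the list alone, preset camera adjusted p = 2.56e-22, adjusted p = 0.474 with an estimated correlation). Rete Control embryos 4, 8, 12 and 14, with ribosomal protein scores from 2.91 to 4.27, were among the rete heads. Per embryo the ribosomal protein score gave an interaction of 1.18 ± 0.40 (permutation p = 0.00751, adjusted p = 0.158). Ribosome biogenesis genes had 52 of 55 positive (median 0.71, 1 adjusted over the list alone, 1.90e-05 and 0.70), pluripotency and first-lineage genes 12 of 19 (median 0.70, 6 adjusted over the list alone, 0.0455 and 0.474) and maternal transcripts 20 of 72 (median -0.41, 0 adjusted over the list alone, 5.90e-11 and 0.473). Heat-shock and unfolded-protein genes had 16 of 20 positive (median 0.74, 1 adjusted over the list alone, 0.025 and 0.474) and RNA-processing and chromatin regulators 43 of 50 (median 0.50, 0.0346 and 0.70). Fry passed for ribosomal protein, pluripotency and first-lineage and heat-shock and unfolded-protein genes (adjusted p = 0.0411 for each).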

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

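The splits of the embryos, the corrections for GC content and stage, the relations with embryo number, reads, detected genes and stage index and the tests of near-identical pairs were chosen after the results were seen. The interaction test itself was planned.

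The diet effect differed between rete and cauda heads for 15 genes (limma interaction, adjusted p under 0.05, 82 embryos): Akirin2 (-2.35), Zmynd19 (-1.67), Siah2 (-1.77), Rac1 (-2.31), Pdxp (-2.77), E2f1 (-1.85), Ybx1 (-1.29), Alyref (-2.54), B4galt6 (-2.38), Tfap2e (-2.39), Suv39h2 (-1.56), Ptov1 (-2.76), Arf6 (-1.98), Srsf2 (-1.95) and Grsf1 (-1.52). Their mean level in log2(CPM + 1) was 6.16 ± 0.58 in cauda Control, 7.09 ± 0.47 in cauda LP, 7.13 ± 0.40 in rete Control and 5.98 ± 0.63 in rete LP embryos.

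Within groups, 24 relations of this mean level were computed. It followed the embryo number in cauda LP embryos (Pearson r = 0.79, permutation p = 1.60e-04, adjusted p = 0.00384, r = 0.70 without the 2 farthest; Spearman rho = 0.82, p = 1.10e-04, adjusted p = 0.00264) and in cauda whole-sperm embryos (r = 0.81, exact p = 0.0075, adjusted p = 0.045, r = 0.79 without the 2 farthest; rho = 0.83, exact p = 0.00827, adjusted p = 0.0496). In cauda Control embryos the relation did not pass adjustment (r = 0.55, permutation p = 0.015, adjusted p = 0.0553, r = 0.42 without the 2 farthest; rho = 0.54, p = 0.0151, adjusted p = 0.0723). Nor did it in rete Control (r = -0.06, rho = 0.00), rete LP (r = -0.26, rho = -0.30) or rete whole-sperm embryos (r = 0.34, rho = 0.23), with adjusted permutation p = 0.325 or more. In cauda LP embryos the level also fell in rank with the stage index (rho = -0.67, permutation p = 0.00458, adjusted p = 0.0366), whereas r was -0.32 (p = 0.2, adjusted p = 0.355) and -0.89 without the 2 farthest. There it was also related to the number of detected genes by r (0.69, permutation p = 0.00224, adjusted p = 0.0179) but not by rho (0.50, p = 0.0424, adjusted p = 0.127), and r was 0.38 without the 2 farthest, so that this relation rests on those 2. In rete whole-sperm embryos the level followed the reads (r = 0.81, permutation p = 0.00182, adjusted p = 0.0179, r = 0.77 without the 2 farthest; rho = 0.80, p = 0.00317, adjusted p = 0.0366).

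For these interaction calls (15 genes, highest other split 2), 1 of 100 splits, the real one, called as many. That does not firmly exclude chance, since 9 comparisons were checked in this way. With 100 splits no share below 1 in 100 can be shown. At an unadjusted limma p under 0.05, 11 of 100 splits had as many genes. Splits of the embryos cannot test a difference between fathers or days, which the labels do not give. Centring by GC content left a mean interaction of -1.94 and the stage index as a covariate -2.05, against -2.07 without either, which argues against GC content or developmental progress as the whole cause, although the level moved with the stage index within cauda LP embryos. Centring ended the calls of Ybx1 (-1.29 ± 0.27 to -1.21 ± 0.31 by GC content and -1.12 ± 0.29 by length), Arf6 (-1.98 ± 0.46 to -1.79 ± 0.48 and -1.81 ± 0.50) and Grsf1 (-1.52 ± 0.37 to -1.41 ± 0.41 and -1.38 ± 0.41), through smaller effects with larger errors, and centring by length that of Srsf2 (-1.95 ± 0.47 to -1.84 ± 0.46), through a smaller effect. An unrecorded day or batch of embryos stays open and may account for part of the pattern, since the level followed the embryo number in cauda LP (rho = 0.82) and cauda whole-sperm embryos (0.83), while no such relation passed adjustment in the rete groups. An exchange of the 2 diet labels within 1 source, or of the 2 source labels within 1 diet, would also give opposite diet effects. Such an exchange stays open, as does a biological difference between diets and sources. Across genes the source effect in Control heads ran against that in whole sperm (r = -0.342, as extreme in 4 of 100 permutations). An exchange of source labels among Control embryos would give that. Medians of ribosomal protein genes were -0.73 and 0.62, with the low rete Control embryos 4, 8, 12 and 14 included. The source effects in Control and LP heads, which that exchange would set against each other, correlated with r = 0.113 (52 of 100). The 15 genes had a mean level of 6.02 ± 0.28 in cauda and 5.89 ± 0.46 in rete whole-sperm embryos. These means lie near cauda Control and rete LP, as an exchange of diet labels in rete heads would give. Single genes do not all do so. Arf6 was at 4.6 and 4.85 in cauda and rete whole-sperm embryos, below every head group (6.51 to 7.66). Tfap2e was at 5.98 and 5.58, above every head group (3.67 to 5.31). The diet effects in cauda and rete heads, which that exchange would set against each other, correlated with r = 0.047 (85 of 100). The preparation differed too and the labels give no father or day, so these values do not decide.

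Chance is not firmly excluded for the 118 genes called for diet in rete heads. As many were called in 2 of 100 splits, the real one included, among 9 comparisons. At an unadjusted limma p under 0.05, 5 of 100 splits had as many genes. The highest other split called 1864 genes, which points to a structure of the samples other than diet. With the stage index as a covariate the median of the 31 higher genes went from 1.36 to 0.6 and 1 stayed past the threshold, so developmental progress may account for the higher genes and cannot be told apart from diet there, because the index itself lay 1.18 ± 0.45 higher in LP embryos (permutation p = 0.0124, adjusted p = 0.122). The median of the 87 lower genes went from -1.28 to -0.92 and 22 stayed, which argues against it as the whole cause of those. The number of detected genes as a covariate left 118 of the 118 past the threshold and averaging the near-identical pairs left 72, which argues against either as the whole cause. A direct effect of the father's diet stays open.

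Rete LP embryos 20 and 21 (r = 0.973) and 22 and 23 (r = 0.945) lay closer than any other pair within a group, where the median over 912 pairs was 0.744. The next pair, rete LP 21 and 23 (0.904), joined 1 embryo of each. The first pair without these embryos was cauda Control 1 and 7 (0.891). The chi-square per gene of the closest pair was 4.39, which argues against a library deposited more than once, for which it would be near 1. It was 6.55 for embryos 22 and 23, and the median over pairs within groups was 38.3. Material shared between neighbouring embryos stays a possible explanation. Without the 2 closest pairs, neighbouring numbers in the rete LP group correlated no more than other pairs (difference -0.002, one-sided permutation p = 0.543). This leaves sharing within those pairs alone, or among embryos 20 to 23, undecided. No biological explanation was tested.

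Cauda whole-sperm embryo 5 stood apart from the other 8 in 3 of 19 measures by Dixon's limit: the score of DNA methylation and imprint-protection genes (4.36), the score of paternally expressed imprinted genes (3.53) and the number of genes at 1 CPM or more (6696). Chance sets apart about 1 in 20 such groups. Rete LP embryo 11, in a group of 23 too large for that limit, was lowest of its group in the number of genes at 1 CPM or more (6095), in the score of DNA methylation and imprint-protection genes (2.51, next lowest 4.59) and in that of sterol synthesis genes (2.33, next lowest 3.98).

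Among the other comparisons, 1 of 100 splits, the real one, called as many genes for the source effect in LP heads (6 genes, highest other 1). There 0 genes passed with these 2 groups alone, and with 9 comparisons checked chance is not firmly excluded. Nor is chance firmly excluded for the source effect in Control heads (3 genes). There 3 other splits called as many or more (4 of 100 with the real one, just under 5). The highest other split called 831 genes, which again points to a structure of the samples. Where no gene was called, all 100 of 100 splits give as many whatever the data, so that their number decides nothing: diet in cauda heads (highest other 2), source in whole sperm (345), diet averaged over sources (1), source averaged over diets (0) and source by preparation (27). Counted at an unadjusted p under 0.05, the splits with as many genes for these 5 were 46, 14, 8, 4 and 4 of 100, and they were 5 for diet in rete heads, 6 and 8 for source in Control and LP heads and 11 for the interaction.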

How the results depend on the processing

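The stage covariate, averaged pairs, GC and length centring and scores of other lists were chosen after seeing the data. Of 4777 alternative values for 312 gene results, 4479 kept direction and side of the threshold, 82 newly passed, 170 no longer passed and 46 changed sign. Of 108 for 18 scores of other lists, 105 were the same and 3 newly passed. The count for whole sperm and for diet averaged over sources stayed at 0 in every alternative run. The cause was not tested for any change below. A fit of the 2 groups alone uses fewer embryos and takes the spread from those groups only. In it, genes at an unadjusted limma p under 0.05 went from 1809 to 1410 for diet in rete heads. They went from 1745 to 1525 and from 608 to 589 for source in Control and LP heads, but from 163 up to 301 for diet in cauda heads. Fewer embryos alone would not be expected to raise that last count. Depth limits genes near 1 read per embryo.

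The diet count in rete heads (118) was 292 with quantile normalization, 348 with median-of-ratios scaling, 44 with array weights, 437 with detected genes as a covariate, 346 without low-gene embryos, 14 with the 2 groups alone, 50 by rank-sum, 47 with the stage covariate, 75 with pairs averaged, 425 and 409 with GC and length centring and 474 at a threshold of 0.1. Array weights gave 14 in cauda heads (0), 17 for source in Control heads (3), 260 in LP heads (6), 74 for the interaction (15), 484 for source averaged over diets (0) and 237 for source by preparation (0). Source in Control heads fell to 1 with GC and 1 with length centring. Source in LP heads was 11 with a pseudocount of 5, 3 with median-of-ratios scaling, 10 without low-gene embryos, 0 with the 2 groups alone, 3 by rank-sum, 16 with the stage covariate, 3 and 1 with GC and length centring and 13 at 0.1. The interaction was 42 with the stage covariate. Source averaged over diets was 1 at 0.1. Source by preparation was 15 with a pseudocount of 0.1, 1 with GC and 1 with length centring and 12 at 0.1. Quantile normalization and median-of-ratios scaling, in this order, moved the median of all genes from -0.142 to -0.005 and 0.025 for source in LP heads, from -0.149 to -0.014 and -0.012 averaged over diets, from -0.098 to 0.025 and 0.01 in Control heads, from 0.098 to -0.02 and 0.017 in whole sperm and from 0.192 to -0.063 and 0.01 for source by preparation.

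Shared embryo numbers did not pair the embryos: deviations of same-numbered embryos correlated with a median r of -0.02, 0.04, 0.05, -0.01 and 0.06 in the 5 pairwise comparisons, and 1, 1, 0, 1 and 1 embryos correlated best with their own number. With the replicate block the counts were 0 for diet in cauda heads, 137 in rete heads, 3 and 8 for source in Control and LP heads, 0 in whole sperm, 16 for the interaction and 0 for the rest.

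The MERVL score for diet averaged over sources (-0.005) was 0.017 with median-of-ratios scaling, 0.015 with the replicate block and 0.005 without low-gene embryos, and for source in Control heads (0.024) -0.047 without low-gene embryos. The log2 fold changes that changed sign belonged to genes that had not passed. For diet in cauda heads, Aqp9 was -0.02 with array weights, -0.078 with detected genes and -0.08 by median difference. For diet in rete heads, Ldhc was -0.046 with a pseudocount of 5, -0.206 with array weights, -0.009 with detected genes, -0.4 with stage and -0.006 with pairs averaged, Usp29 -0.003 by median difference and -0.262 with stage, and Gata4 -0.173 with stage. For diet averaged over sources, Ldhc was -0.003 with array weights and -0.116 with stage, and Amhr2 -0.092 with stage. For source in Control heads, array weights gave Hist1h3f -0.021 and Gata4 0.059, the median difference Odf2 -0.079, and stage Hist1h3f -0.089, Sesn2 0.08, Ldhc 0.035, Odf2 -0.071, Gata4 0.417 and Amhr2 0.271. For source in LP heads, Hist1h3f was 0.06 with quantile normalization, 0.144 with array weights and 0.005 with length centring, Gata4 0.03 and Serpine2 0.124 with array weights, Hist2h3c1 0.003 and Gja1 -0.005 with the block, Eno1 0.092 and Gata4 0.087 by median difference, and Hist2h3c1 0.037 with length centring. For source in whole sperm, Gata4 was -0.081 with detected genes, -0.085 without low-gene embryos and -0.105 with stage, and Hist1h1a 0.029 by median difference. For source averaged over diets, Hist1h1a was 0.056 with quantile normalization, 0.038 with the block, 0.064 with GC and 0.013 with length centring, Gata4 0.044 with array weights and 0.061 with stage, and stage gave Gnas -0.034, Amhr2 0.211 and Gja1 0.115. The count-based test planned for tables of counts was not run, since the values were not whole reads.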

Other observations

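The neighbour test, the relations along the main axis and the correlations of fold changes were chosen after the data were seen.

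The largest axis of variation over all embryos held 36.6% of the variance and the next 8.2%. Its ends were named late and early by its correlation with the stage index (r = 0.991), not by an observed stage. Genes at its late end included Tbl3 and Bop1 of the nucleolus, Usp22 and Gata1, and genes at its early end Gm4302 and Zscan4b. Bop1 is itself a member of the ribosome biogenesis list that enters the index. The stage index, the ribosome biogenesis score minus the maternal score, was -0.31 ± 1.38 in cauda Control, -0.17 ± 1.32 in cauda LP, -1.46 ± 1.82 in rete Control and -0.28 ± 1.13 in rete LP embryos. It was -3.54 ± 0.98 in cauda and -2.93 ± 0.82 in rete whole-sperm embryos, which had also been sequenced more deeply. None of 18 tests of the index or the axis passed adjustment (smallest adjusted p 0.122), and heads were not tested against whole sperm because the labels give no day.

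Across genes, which are not independent, the source effect in Control heads and in whole sperm correlated with r = -0.342, as extreme in 4 of 100 permutations of the labels, the source effects in Control and LP heads with r = 0.113 (52 of 100) and those in LP heads and whole sperm with r = 0.149 (30 of 100). Among rete whole-sperm embryos, neighbouring numbers correlated at 0.789 and other pairs at 0.753 (difference 0.036, one-sided permutation p = 0.00179, adjusted p = 0.0125 over 7 tests). In the other 5 groups the adjusted p was 0.231 or more.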
